A study of Oncorhynchus mykiss with 19 samples.

How the data were processed

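The samples were 19 membrane arrays hybridised with cDNA labelled with radioactive phosphorus, reverse transcribed from the total RNA of muscle of single rainbow trout, per the labels' protocols. Groups were taken from the source name of each sample. For 3 L-LE samples the diet label names a high fat diet beside LE and 10% lipids. They were kept in L-LE, because the source name, the group label and the lipid share all give LE, and the comparisons were repeated without them. Arrays are named by group and a replicate number given in the order of deposition, which pairs no samples. The labels describe the fish as biological replicates, kept in 2 or 3 tanks per group.

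The deposited scanner files hold the spot intensity within a fixed diameter, quantified from the membrane image by AGScan, per the file headers. They hold one signal per spot, from the image and from a fitted spot, with no background and no vector oligonucleotide signal, and no scaling is recorded in them. The authors' value table holds deposited log10 values. Per the series text, the authors left out spots whose vector oligonucleotide signal was under 3 times the background, corrected each spot for the DNA it held and divided by the array median. The log base is not stated in the sources used here. For 3699 clones matched to 1 spot by profile, the median slope of the table on log10 signal was 0.971, with quartiles of 0.909 and 1.04, so the table was read as log10. The median of each of its columns is 0. An exact 0 stood in 690 of 9216 rows on all arrays and in 1072 rows on some arrays, and was 0 on all arrays for 60 of 64 blank rows, so an exact 0 was taken as a spot left out.

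The DNA correction and the filter on the vector signal, which had been planned for the scanner signal, were skipped, since the scanner files hold no vector signal. The main values were log2 of the image signal minus the array median, for all 9216 spots. Control spots carry no name in the scanner files and stayed in. The authors' table, after removal of the blank rows and of 128 rows named CVU03687, was the alternative that holds the DNA correction. It gave 7693 clones of 9024 with values on at least 3 arrays of every group. A spot was matched to a clone where each was the other's best by Pearson's r over the arrays. The r had to be at least 0.9, with a gap of at least 0.05 to the clone's next spot. No such gap was required to the spot's next clone. No file pairs spots with clones, so a clone ID given beside a spot rests on this match alone, and its DNA-corrected values are not independent of it.

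One limma model (version 3.58.1 in R 4.3.3) with a mean for each of the 4 groups was fitted to all arrays, with an intensity trend in the prior. The 7 contrasts were the line effect (F minus L, mean of both diets), the diet effect (HE minus LE, mean of both lines), their interaction, and each effect within 1 diet or 1 line. Tests were two-sided, with Benjamini-Hochberg adjustment over all spots and a threshold of adjusted p 0.05. Up to 2 spots of smallest p in each direction are named per contrast, by a rule set before the data were examined for the case that no gene names are given. Gene lists set at that time could not be tested, since they need gene names. The design, the contrasts and most alternatives were also set before the data were examined.

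The model was tested on simulated data made from the spot means and spreads, with independent errors. For each contrast, 50 spots were changed by each of the folds 1.5, 2, 3 and 4 in the same data. The shares recovered hold for data in which all these spots change at once. Where few spots change, the adjusted threshold is stricter, so these shares overstate the recovery of a lone changed spot. For the line effect it recovered 90% of spots changed 2-fold and 60% of those changed 1.5-fold. For the diet effect the shares were 88% and 44%. For the interaction it recovered 32% at 2-fold and 84% at 4-fold, for the diet effect in the L line 68% at 2-fold, and for the line effect on the HE diet 56% at 2-fold. Unchanged spots called ran from 4 for the diet effect in the L line to 10 for the interaction.

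The alternatives were the authors' values, quantile normalization, a filter on dim spots, array weights, no trend in the prior, tank as a random block (correlation within tanks -0.0389), the last number of the sample title as a block, arrays with a title number under 50 or of 50 and over alone, single arrays left out, and fits of 2 groups alone. In the first of these restrictions F-LE and L-HE hold 1 array each, taken to vary like the other groups. The comparison of these single arrays with the rest of their groups, and the counts at an unadjusted p under 0.01 in each alternative, were chosen after the result was seen. The title number is under 50 on 9 arrays, among them all 5 L-LE arrays, and 50 or over on 10. Its meaning is not stated in the sources used here. It was treated as a possible membrane series. A first test of that series counted spots with the series as a block, and a second, chosen after the first had been seen, correlated its effect with a contrast. Both are given. The correlation within tanks is 1 value over all spots, so that alternative cannot show whether tanks differ at a single spot. Figures were drawn with matplotlib 3.10.9.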

Results

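Muscle RNA of rainbow trout (Oncorhynchus mykiss) was compared between 2 lines of fish selected in opposite directions for muscle fat, the lean L line and the fat F line, each fed a low fat diet (LE, 10% lipids) or a high fat diet (HE, 23% lipids) for 6 months from first feeding. Per the labels, each array carried the labelled cDNA of the muscle of 1 fish. The 19 arrays comprised 5 F-LE, 4 F-HE, 5 L-LE and 5 L-HE fish, and their number limits the precision. Each group was kept in 2 or 3 tanks, and the main tests treat the fish of a tank as independent. The extraction protocol in the labels speaks of 8 samples per condition, and why 4 or 5 per group are in hand is not stated in the sources used here. Each array was a membrane of 9216 spots in 64 print blocks, read as the radioactive signal of each spot. The median spot signal lay between 43 and 140 per array, and at most 15 spots of an array reached the top of the scale. Pearson's r of log2 signal over all spots was between 0.911 and 0.973 for pairs of arrays, with a median of 0.948 within groups and 0.945 between groups. The deviations of a spot from its group means had a median SD of 0.36 on the log2 scale. Spots are named by grid position. The files used here pair neither spots nor clones with gene names, so no change is given for a named gene or pathway. A clone ID beside a spot comes from matching the spot's profile over the arrays to the authors' value table.

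The effect of selection on fatness was asked as the difference between the F and L lines over both diets. Spot C01-D09 was higher in the F line, by 1.36 ± 0.21 (SE) on the log2 scale or 2.56-fold (limma, adjusted p = 0.00753), and was the 1 spot of 9216 that passed the threshold. Its level over the array median, on the log2 scale, was 3.59 ± 0.21 (SD, n = 5) in F-LE, 2.89 ± 0.72 (SD, n = 4) in F-HE, 2.80 ± 0.40 (SD, n = 5) in L-LE and 0.97 ± 0.54 (SD, n = 5) in L-HE. Its profile matched clone 1RT109B14_D_A07 with r = 0.989, against 0.846 for the clone's next spot. In the authors' DNA-corrected values this clone had a line effect of 1.27 ± 0.21 (SE, adjusted p = 0.0147). Among the spots that did not pass, those with the smallest p in each direction were E01-H11, G04-K08 and H04-C08. Their log2 differences were 0.63 ± 0.15 (SE), -0.59 ± 0.16 and -0.63 ± 0.18, each at an adjusted p of 0.807. By profile they matched clones tcay0020.g.19, tcbk0016.h.18 and 1RT83P06_D_H03. For 98.1% of all spots, the 95% interval of the line effect lay within 2-fold either way. This bounds the spot signal, with no background subtracted and control spots included, and not the change of each transcript. At an unadjusted p under 0.01 there were 105 spots, where 92 are expected if no spot differs. With quantile normalization the line effect of C01-D09 was 1.23 ± 0.22 (adjusted p = 0.0924), and without the 3 L-LE arrays whose diet label contradicts itself it was 1.15 ± 0.25 (adjusted p = 0.573), so that it passed in neither. Those 3 arrays are all the L-LE arrays of tank 3, and C01-D09 was lower in them than in the L-LE arrays of tank 1. That alternative thus removes a tank as well as a label.

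**Figure D1:**
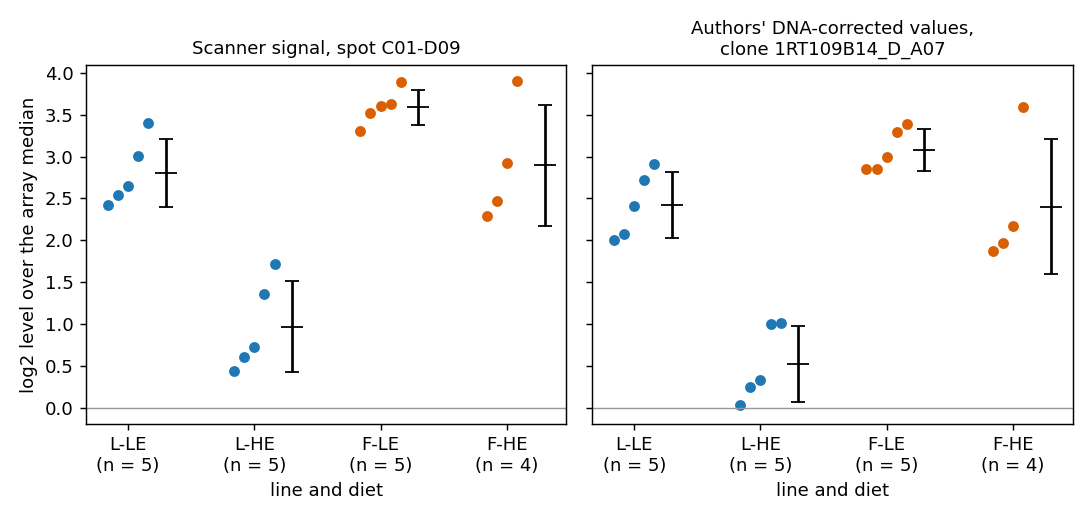
Level of spot C01-D09 in the scanner signal (left) and of clone 1RT109B14_D_A07 in the authors' DNA-corrected values (right), as log2 over the array median, by line and diet. Points are arrays in order of value, and bars give the mean ± SD of the group. The 5 L-HE arrays lie between 0.44 and 1.72 in the scanner signal, below the arrays of every other group.

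The effect of dietary lipid was asked as the difference between the HE and LE diets over both lines. C01-D09 was again the 1 spot that passed. It fell by 1.26 ± 0.21 (SE) on the log2 scale on the HE diet, a 2.40-fold difference (limma, adjusted p = 0.0231). The authors' values of clone 1RT109B14_D_A07 gave -1.29 ± 0.21 (SE, adjusted p = 0.0113). The next spots in each direction did not pass. H03-J02, which matched clone tcbk0013.g.16, had a log2 difference of -0.77 ± 0.18 (adjusted p = 0.740). G01-C12 and O01-L09, which matched no clone, had 0.65 ± 0.16 and 0.56 ± 0.15 (both adjusted p = 0.9998). The 95% interval of the diet effect lay within 2-fold either way for 98.8% of the spots, again as a bound on the spot signal alone. At an unadjusted p under 0.01 there were 66 spots against 92 expected. With 1 array left out this count ran from 33 without F-HE replicate 1 to 87 without F-HE replicate 2. With 1 array left out in turn, the log2 change stayed between -1.43 and -1.16 in all 19 cases. The call was not stable, and ended in 12 of them (limma, adjusted p up to 0.136). It also ended with the last number of the sample title as a block, at -1.25 ± 0.23 (adjusted p = 0.0831), and without the 3 L-LE arrays of contradictory label, at -1.47 ± 0.25 (adjusted p = 0.0520).

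Whether the lines responded differently to the diet was tested as the interaction, the diet effect in the F line minus that in the L line. No spot passed in limma with all 19 arrays. There were 154 spots at an unadjusted p under 0.01 (92 expected) and 616 under 0.05 (461 expected). The former count was 92 without F-HE replicate 4 and 94 without the 3 L-LE arrays of contradictory label, close to the 92 expected, and up to 199 with another array left out. For C01-D09 the interaction was 1.14 ± 0.43 (SE) on the log2 scale, with an unadjusted p of 0.0125 and an adjusted p of 0.625. The spots of smallest p in each direction were E03-B06 with 1.04 ± 0.27, N03-F03 with 1.08 ± 0.29, N02-C03 with -1.50 ± 0.36 and O01-A12 with -1.69 ± 0.42. Each had an adjusted p of 0.522. By profile N03-F03 matched clone tcad0009.o.03 and N02-C03 matched 1RT99L23_B_F12. The interaction had the widest error of the comparisons, with a median SE of 0.33 on the log2 scale, and its 95% interval lay within 2-fold either way for 55.9% of the spots. With the 9 arrays of title number under 50 alone, where F-LE and L-HE had 1 array each, 7 spots passed for the interaction, 12 for line and 9 for diet, but not C01-D09. At each of these 14 spots the single F-LE or L-HE array lay outside the range of its group's other arrays. At 11 of them the F-LE array lay above all other F-LE arrays. On the membrane 7 of them touched another of these spots, so they are not all separate calls.

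Within the L line, C01-D09 fell by 1.83 ± 0.29 (SE) on the log2 scale on the HE diet, a 3.57-fold difference (limma, adjusted p = 0.00937), and no other spot passed. The 5 L-HE arrays, at 0.44 to 1.72 over the array median, all lay below the 5 L-LE arrays, at 2.42 to 3.41. Within both L groups C01-D09 also separated by tank. L-LE was at 2.42 to 2.64 in tank 3 and 3.01 to 3.41 in tank 1. L-HE was at 1.36 to 1.72 in tank 3 and 0.44 to 0.72 in the other tanks. In F-HE the tanks overlapped. In F-LE the tank 1 array lay within the range of tank 3 and the tank 2 array above it. Fish of a tank may thus not be independent replicates. G01-L03 (clone tcbk0056.a.13) had a difference of 1.07 ± 0.22 (adjusted p = 0.154), I01-B03 (1RT66H09_B_D05) had 0.96 ± 0.21 (adjusted p = 0.229) and H03-I09 (tcba0008.c.20) had -0.82 ± 0.23 (adjusted p = 0.587). With the title number as a block, the change of C01-D09 was -1.78 ± 0.37 (adjusted p = 0.30), and the call also ended without any 1 of 4 single arrays or without the 3 arrays of contradictory label (-2.24 ± 0.39, adjusted p = 0.0706). Those 3 arrays are the L-LE arrays of tank 3. Within the F line no spot passed in limma, with 46 spots at an unadjusted p under 0.01 (92 expected) and 324 under 0.05 (461 expected). C01-D09 had a diet effect of -0.69 ± 0.31 there (adjusted p = 0.99989), and the test of the difference between the lines is the interaction given above. The F-line spots of smallest p in each direction were P01-E07 with 0.75 ± 0.20, O02-D08 (1RT107M11_A_G06) with 0.91 ± 0.24, H03-J02 with -1.14 ± 0.26 and L03-C10 (1RT88B23_B_A12) with -0.81 ± 0.24. Each had an adjusted p of 0.99989.

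On the HE diet, C01-D09 was higher in the F line than in the L line by 1.93 ± 0.31 (SE) on the log2 scale, or 3.80-fold (limma, adjusted p = 0.0112), and no other spot passed. All 4 F-HE arrays, from 2.29 up, lay above all 5 L-HE arrays. D01-H11 had a difference of 1.28 ± 0.32, H01-F04 (tcad0009.g.03) of -0.84 ± 0.20 and G03-E12 of -1.01 ± 0.26, each at an adjusted p of 0.736. Among arrays with a title number of 50 and over, the line difference of C01-D09 on this diet was 1.59 ± 0.35 (adjusted p = 0.497), and a fit of these 2 groups alone gave an adjusted p of 0.132, so that the call ended in both. It also ended when any 1 of 5 single arrays was left out. On the LE diet no spot passed in limma, with 134 spots at an unadjusted p under 0.01 (92 expected) and 731 under 0.05 (461 expected). Single arrays moved the former count by over 1.5 times, to 72 without F-LE replicate 3, 84 without L-LE replicate 4, 86 without F-LE replicate 1 and 238 without L-LE replicate 5. C01-D09 had a line effect of 0.78 ± 0.29 there (adjusted p = 0.614). O03-C03 had 1.46 ± 0.29 (adjusted p = 0.243). P01-E12 had 1.01 ± 0.23, J01-L05 had -0.77 ± 0.21 and A04-G01 had -1.11 ± 0.31 (adjusted p = 0.614 for these 3 spots).

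**Figure D2:**
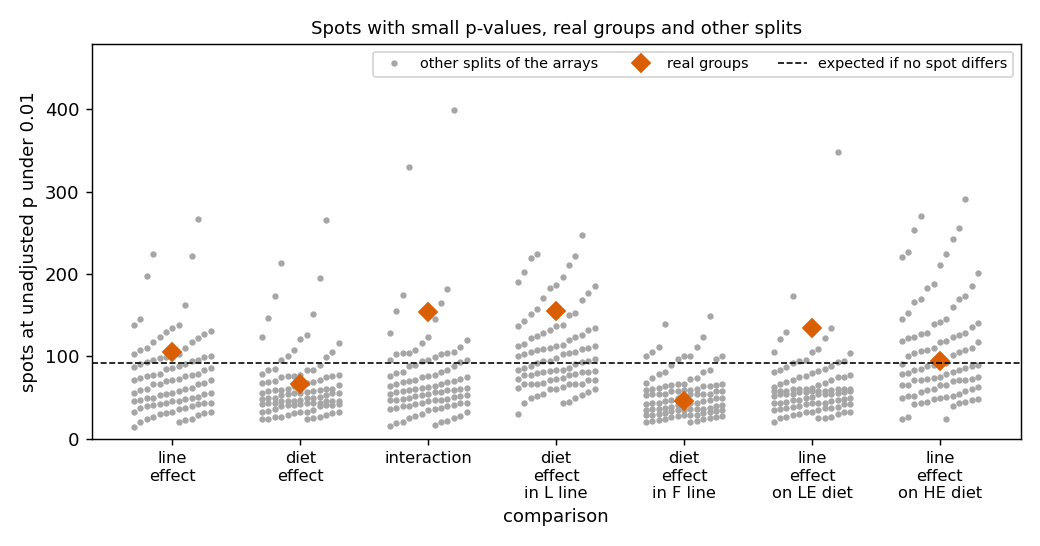
Number of spots at an unadjusted p under 0.01 (vertical axis) in each comparison (horizontal axis), for the real groups (diamonds) and for other splits of the same arrays into groups of the same sizes (dots, spread sideways). The dashed line is the 92 spots expected if no spot differs, and the real counts run from 46 to 155.

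The counts at an unadjusted p under 0.01 depended on the processing. In the order line, diet, interaction, diet in the L line, diet in the F line, line on the LE diet and line on the HE diet, the authors' values gave 102, 38, 102, 95, 52, 101 and 105 clones (77 expected), quantile normalization gave 74, 65, 102, 154, 36, 65 and 115 spots (92 expected), and the title number as a block gave 97, 50, 62, 67, 40, 72 and 81 (92 expected). Without the dimmer part of the spots, those with a mean level below the median spot, they ran from 26 for diet in the F line to 117 for the interaction (46 expected). Array weights raised the count to 265 for line on the LE diet and to 101 for diet in the F line (92 expected).

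Across all 9216 spots, the diet effect in the L line correlated with the diet effect in the F line at Pearson's r = -0.137 and Spearman's rho = -0.141. Spots are not independent replicates, so r was set against all 31752 regroupings of the arrays between diets within lines, of which 95% gave values between -0.205 and 0.205 (exact permutation p = 0.197, 0.395 after Benjamini-Hochberg adjustment over 2 relations, two-sided). The line effects on the LE and HE diets correlated at r = -0.0117 and rho = -0.0129 (exact permutation p = 0.893 before and after adjustment). With all 19 arrays, neither differed from 0 by more than regrouping gave. For the diet effects this rested on single F-HE arrays, with r = -0.244 without F-HE replicate 1 (exact permutation p = 0.0164, unadjusted) and r = -0.0224 without F-HE replicate 4 (exact permutation p = 0.831, unadjusted).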

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

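The splits of the arrays and the correlations with the title-number effect were set before their values were seen, the correlations after the count with the title number as a block. The tests of DNA amount, neighbouring light and title number on C01-D09, the count with the title number as a block, and the adjustment of the splits over the comparisons, were chosen after the result was seen.

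The diet effect on spot C01-D09 differed between the lines by the unadjusted test alone, with an interaction of 1.14 on the log2 scale (limma, unadjusted p of 0.0125, adjusted p of 0.625). This interaction was 1.07 ± 0.53 (SE) with the title number as a block, and 0.81 at the lowest with 1 array left out. A single array stood apart from the others of its group at 4 of the spots named, by the gap to its nearest neighbour as a share of the range. E03-B06 was at -0.14 in F-HE replicate 4, where the nearest array was at -0.040. H03-I09 was at 0.046 in F-LE replicate 5, where the nearest was at -0.74. A04-G01 was at -1.20 in F-LE replicate 5, where the nearest was at -1.0. Its spread was wider in L-LE, the group F-LE was compared with, at an SD of 1.07 against 0.11 in F-LE. H01-F04 was at 0.12 in L-LE replicate 4, where the nearest was at -0.45. These are 4 of 104 groups tested, and chance gives about 5.2.

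C01-D09 is a candidate for a transcript that differs by line and diet. An unequal amount of DNA in its spot is argued against as the whole cause by the authors' DNA-corrected table, where among all 7693 clones, without use of the profile match, the only clone called had a line effect of 1.27 ± 0.21 (SE) log2 and was called in the same 4 comparisons and directions as C01-D09. Light from a neighbour is argued against by the 8 touching spots, the brightest of which averaged -0.099 against 2.55 for C01-D09. With the title number as a block the line effect was 1.37 and passed, and the diet effect was -1.25, almost the size without it (-1.26), but its SE rose from 0.21 to 0.23 and the call ended at an adjusted p of 0.0831, so a membrane series is not the whole of either. C01-D09 also separated by tank within both L groups. The tank alternative used a single correlation over all spots, so it cannot decide whether tanks add to either effect. A line or diet effect on the transcript stays open as a hypothesis, found and tested on the same data, and the clone rests on a profile match.

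Other splits of the arrays into groups of the same sizes, 100 per comparison with the real one, bear on whether chance can be excluded. For counts of spots called, the fewest splits were as large for the line effect (1 split, the real one, with 1 spot called against 0 at most in the others). The diet effect (3 splits, 1 against 1) and the diet effect in the L line (3 splits, 1 against 1) came next. Chance is not excluded for any of them, since after Benjamini-Hochberg adjustment over the 7 comparisons each of these shares is 0.07. For the line effect this reflects the number of splits drawn, since 100 splits give no share under 0.01. Chance cannot be excluded for the line effect on the HE diet either (9 splits, 1 against 13). A split of the F-LE and F-HE arrays called 10 spots where the real groups called 0. Such counts, several times the real one, may come from groups of arrays or from spots that vary together, which was not tested. On each array, the deviations from the group means were correlated with the mean level of the spots. Spearman's rho ran from -0.537 in F-LE replicate 4 to 0.483 in L-LE replicate 5. These arrays lay in opposite arms in the highest splits at p under 0.01 for line, diet, interaction and line on the LE diet. Whether this dependence on spot level gave the counts was not tested. For counts at an unadjusted p under 0.01, the line effect on the LE diet had the fewest splits as large (4 splits, 134 spots against 348 at most in the others). Its share is 0.245 after the same adjustment, so chance is not excluded for this count. That count moved both ways with the processing, to 65 with quantile normalization, 72 with the title number as a block, 183 with tank as a random block, 188 without the trend in the prior and 265 with array weights (92 expected in each), and 101 in the authors' values (77 expected), and with 1 array left out it ran from 72 to 238. Nor can chance be excluded for the line effect (20 splits, 105 against 267), the diet effect (36, 66 against 265) or the interaction (7, 154 against 399). The same holds for the diet effect in the L line (16, 155 against 247), the diet effect in the F line (56, 46 against 149) and the line effect on the HE diet (46, 95 against 291).

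The 3 comparisons that L-LE enters with full weight (diet in the L line, line on the LE diet, interaction) had 155, 134 and 154 spots at p under 0.01, more than the other 4, and all L-LE arrays have a title number under 50. In the authors' values they had 95, 101 and 102, against up to 105 for the other 4, so the excess depends on the values used. For diet in the L line the count was 87 in a fit of these 2 groups alone and 96 with the fitted-spot signal (92 expected). For line on the LE diet these gave 143 and 144, and the fitted-spot signal gave 137 for the interaction. The split of the LE arrays that gave 348 spots followed the title number as closely as the lines do. It had 0 of 5 arrays at 50 or over in 1 arm and 4 of 5 in the other. It was the real line split with F-LE replicate 4 and L-LE replicate 5 exchanged, so it is not separate support for a membrane series. These arrays were also the extremes of the correlation of deviations with spot level, at -0.537 and 0.483. Whether a membrane series acts apart from that dependence was not tested. Within groups, the title number itself gave 235 spots at p under 0.01 (92 expected) and 1 called in limma. This was B03-K01 (-1.59, adjusted p = 0.0104), singled out after its values were seen. Across spots, the line effect on the LE diet correlated with the title-number effect of the HE arrays, which it does not use, at r = 0.254, the highest of 30 regroupings (one-sided exact permutation p = 0.033, the smallest possible), and the diet effect in the L line with that of the F arrays at r = 0.248 (p = 0.067), both 0.067 after adjustment over the 2. With the title number as a block the count for the diet effect in the L line fell to 67, but the block's wider SE applied to the effects without it gave 21, so that fall decides nothing. A membrane series may thus explain part of the small p-values on the LE diet, it cannot be told apart from diet in the L line, and a biological difference of L-LE fish stays open.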

How the results depend on the processing

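Fitted-spot signal, print-block centring, image-name suffix, authors' values with title block, the stricter dim filter and the alternatives to correlations and to counts at p under 0.01 were chosen after seeing the data. C01-D09 kept its direction throughout, with a line effect of 1.15 to 1.87 (past threshold in 30 of 33) and a diet effect of -1.58 to -1.16 (17 of 33). Diet in the L line passed in 26 of 33 and line on the HE diet in 27 of 34. The other 24 named values kept theirs in 755 of 755 results, of which 3 passed. All these spots were picked for small p on the same arrays, so a kept direction is no separate support. Counts called became 0 with quantile normalization (line), with the title block (diet), with the authors' values and title block (diet, diet in the L line), without the 3 arrays of contradictory label (line, diet, diet in the L line), and with title numbers of 50 and over or 2 groups alone (line on the HE diet). Leaving out arrays lowers n, and leaving out the 3 of contradictory label also removes all L-LE arrays of tank 3. Other causes were not tested. Without the trend in the prior, 2 were called for diet in the L line (G01-L03 added). With the title block 1 was called there, I03-C11 (1.88, adjusted p = 0.0183) in place of C01-D09. I03-C11 was at 2.56 in the single L-HE array of title number under 50, and at -0.12 to 0.21 in the other L-HE arrays. All L-LE arrays are under 50, so this call may rest on that array. With title numbers under 50 alone, 12 (line), 9 (diet) and 7 (interaction) spots were called, C01-D09 in none (adjusted p of 0.137, 0.299 and 0.99992).

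The count at an unadjusted p under 0.01 over that expected from the spots or clones tested ranged over the alternatives from 0.72 to 1.51 for line (before 105 spots, or 1.14), 0.36 to 1.52 for diet (66, 0.72), 0.67 to 2.54 for the interaction (154, 1.67), 0.73 to 2.32 for diet in the L line (155, 1.68), 0.33 to 1.10 in the F line (46, 0.50), 0.71 to 2.88 for line on the LE diet (134, 1.45) and 0.66 to 2.08 on the HE diet (95, 1.03).

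With each array left out in turn, counts called were 1 to 2 (line), 0 to 1 (diet, line on either diet) and 0 to 2 (diet in the L line), and 0 for the interaction and diet in the F line. For diet the call ended in 12 cases: F-LE replicates 1 to 4, F-HE replicates 1 to 3, L-HE replicates 3 to 5 and L-LE replicates 4 and 5 (adjusted p up to 0.136). For diet in the L line it ended without L-HE replicates 3 to 5 or L-LE replicate 5 (up to 0.0732), and for line on the HE diet without F-HE replicates 2 or 4 or L-HE replicates 3 to 5 (up to 0.150). Without L-HE replicate 1, N02-E11, like I03-C11 named after its values were seen, was added for line (1.04, adjusted p = 0.0336) and G01-L03 for diet in the L line (1.19, adjusted p = 0.0477). Without F-LE replicate 3, O03-C03 was called for line on the LE diet (1.68, adjusted p = 0.0261). The correlation of the diet effects in both lines ranged from -0.244 without F-HE replicate 1 (exact permutation p = 0.0164) to -0.0224.

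Not run were normexp, filters on vector signal and missing values (not in the scanner files), title numbers under 50 alone within 1 line or 1 diet (under 2 arrays in an arm) and the gene lists.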

Other observations

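The test in this part was chosen after the result was seen.

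Touching spots varied together across fish. For spots below the array median, deviations from the group means correlated at a median r of 0.473 between side neighbours and 0.278 between spots 5 columns apart in the same print block. For spots at 1 to 4 times the median the values were 0.602 and 0.324. Position on the membrane, such as local background or uneven hybridisation, may be a source of this, and the test cannot separate these. The print blocks took between 11.1% and 32.6% of the deviations' variance on an array. No biological explanation was tested.

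Spots beside a very bright spot were bright too. Of 770 spots 1 column from a spot over 16 times the array median, 0 lay below the median and their median level was 2.47 on the log2 scale, while 48.3% of those 5 columns away lay below it. The 4 side neighbours of C01-D09 followed it across arrays with r between 0.593 and 0.731.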
